A study of Homo sapiens with 13 samples.

How the data were processed

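Expression was measured by 3' end RNA sequencing in 13 tumours, 7 overt GIST from the clinic and 6 mini GIST under 1 cm from autopsies, each labelled as a separate sample. Per the labels' protocols, RNA came from cores of formalin-fixed, paraffin-embedded blocks, polyadenylated RNA was selected with oligo(dT) and heat-sheared, and short reads from the fragment ends were sequenced on an Illumina instrument. The genome build was hg19, per the submitters' processing notes. The aligner, counting program, annotation and use of strand were not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies such as ribosomal protein genes and their pseudogenes, could not be told apart.

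The authors deposited 1 table of 22144 gene symbols by 13 columns, 1 per tumour. Its name calls the values TPM, and the tests were designed for that unit before the data were examined. The values deposited by the authors are RPM (reads per 1000000 reads assigned to genes). Each column summed to 1000000, its values were whole multiples of 1 step shared by all genes, with no division by gene length, and 100% of values came out as whole reads within 0.05 read. Total reads recovered from the steps gave the depth of each library. The log-scale test planned for TPM suits RPM as well and was kept.

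Values were analysed as log2(RPM + 1), so a fold change is a difference of mean logs on that scale. It understates the change of low genes, and where tumours of a group differ widely it can exceed the fold of the mean levels. XIST, TSIX and Y-linked genes, 102 in all, were removed first, and genes were kept where RPM was at least 1 in at least 6 of 13 tumours, whatever their group, which left 12749 and removed 9293. The comparison, overt minus mini GIST, was fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend, no covariate), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Group and tissue source are fully confounded. The p-values of single genes set a difference against the spread between tumours within these groups.

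Gene lists numbering 28 were fixed before the data were examined, covering tumour lineage and signalling, cell types of the gut wall, blood and immune cells, and metabolic and stress programmes; 7 symbols stood in more than 1 list. The 25 lists with at least 5 measured members were tested with limma's camera (inter-gene correlation preset at 0.01, and again estimated), and the mean of each list per tumour was tested with an exact two-sided permutation test over all assignments of tumours to groups. Both were adjusted over the 25 lists. Camera sets the genes of a list against all other tested genes, and its preset correlation treats them as nearly independent. Its p-values with that setting therefore do not take tumours as the replicates. Members were also adjusted over the list alone. A gene is called measured here only if it passed the filter on low values, so further list genes had deposited values below it. Chromosome sets, 24 in number, were tested by camera in the same way. Chromosomes came from the GRCh38.p14 RefSeq gene table, in which 18478 symbols matched directly, 2578 through a synonym and 1088 not at all. No coordinates are given because the builds differ. Distances between tumours were 1 minus the Spearman correlation over tested genes, compared by exact permutation tests.

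Genes named were chosen by a rule fixed in the same way. It took the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 10 RPM in the higher group, 10 genes of interest in GIST whatever their result (KIT, ANO1, ETV1, PRKCQ, PDGFRA, CD34, MKI67, TOP2A, CDKN2A and DMD), and up to 3 members of each list with the smallest p. RN5-8S1, HBB, CNN1 and ACTA2 fall outside it and were chosen after their values were seen. So were the genes named only in the sections on flagged results and other observations.

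Alternatives were pseudocounts of 0.25 and 5, no filter and a filter at 5 RPM, TMM, quantile and median-of-ratios scaling, array weights, an exact rank-sum test, the smooth muscle mean or the number of genes detected as a covariate, leaving out each library in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Another 4 were added after the data were seen: thinning all libraries to 2064816 reads, leaving out overt GIST 6 and 7 together, the exact test of chromosome means per tumour, and other sets of HOXC genes in the relation with BARX1. The outcome was recomputed for 100 splits of the tumours into groups of 7 and 6. The limma step was tested on simulated reads for this comparison, over 13055 genes with 200 changed: it recovered 64.9% of the 97 tested genes changed 4-fold and 100% of those changed 16-fold, with 12 false calls among 175. The simulated genes were independent and had the same dispersion in both groups, so these rates may not hold for the real tumours.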

Results

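Gastrointestinal stromal tumours (GIST) are mesenchymal tumours of the gut wall of the lineage of the interstitial cells of Cajal, its pacemaker cells. The series compared 7 overt GIST obtained from the clinic with 6 mini GIST, lesions under 1 cm across found at autopsy, by sequencing the 3' ends of polyadenylated transcripts from cores of fixed, paraffin-embedded tissue. The question set by the design was how the expression profiles of the groups differ. Each library held between 2064816 and 15573532 reads assigned to genes, with a median of 7957245 in overt GIST and 9654741 in mini GIST, and between 14388 and 17382 genes were detected. The shallowest library was overt GIST 1. A level of 3 reads, used as the floor, stood at 0.193 to 1.45 RPM (reads per 1000000 reads assigned to genes) depending on the library, which covers counting error only. The 10 most abundant genes took 10.2% to 18.2% of the reads. The transcript annotated as 5.8S ribosomal RNA, RN5-8S1, averaged 29200 ± 22530 RPM (SD, n = 7) in overt GIST and 11120 ± 6956 RPM (SD, n = 6) in mini GIST. The difference was within the spread between tumours (limma, adjusted p = 0.395). Every overt GIST came from the clinic and every mini GIST from an autopsy, so the group and the source of the tissue cannot be told apart in any comparison given here.

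Mini GIST resembled each other more closely than overt GIST did. Over the 12749 genes tested, the Spearman correlation between pairs of mini GIST lay between 0.90 and 0.94, whereas pairs of overt GIST lay between 0.78 and 0.89 and pairs of an overt with a mini GIST between 0.76 and 0.88. These correlations run across genes, which are not independent replicates. The mean distance, 1 minus the correlation, was 0.161 within overt GIST and 0.0786 within mini GIST, a difference of 0.0829 (exact permutation test over all assignments of the 13 tumours to the groups, two-sided, p = 0.000583, the smallest it can give). The mean distance between groups, 0.16, exceeded the mean over all pairs within groups by 0.0336 (exact permutation p = 0.00233). It did not exceed the mean within overt GIST, 0.161, so the excess came from the close pairs of mini GIST. The second principal component, with 20.9% of the variance, separated the groups (exact permutation p = 0.00175, Benjamini-Hochberg adjusted over 4 components 0.00699). The first, with 24.9%, did not (p = 0.0693, adjusted 0.139, exact permutation).

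**Figure D1:**
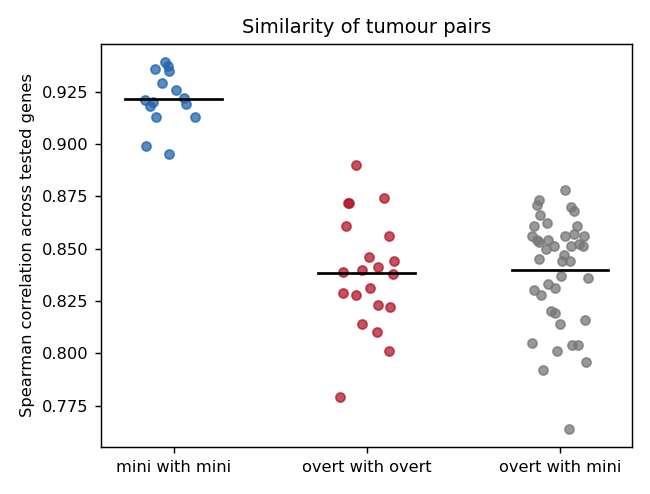
Spearman correlation across the 12749 tested genes (vertical axis, no unit) for each pair of tumours, by kind of pair (horizontal axis). Points are pairs and black lines their means, which were 0.921 for mini with mini, 0.839 for overt with overt and 0.84 for overt with mini.

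The genes with the lowest fold changes in overt relative to mini GIST included DPT, DES, BARX1 and CCND1. DPT, which encodes the extracellular matrix protein dermatopontin, averaged 142.9 ± 332.4 RPM in overt and 2961 ± 1646 RPM in mini GIST (log2 fold change -7.58 ± 1.19, SE; limma, adjusted p = 0.00315; n = 7 and 6). DES, encoding the muscle intermediate filament desmin, averaged 46.1 ± 62.2 against 1496 ± 1151 RPM (-6.31 ± 1.07, adjusted p = 0.00561). CCND1, encoding cyclin D1 of the G1 phase, averaged 146.9 ± 191.1 against 1227 ± 630 RPM (-3.68 ± 0.57, adjusted p = 0.00305). Each of these 3 genes was lower in all 7 overt GIST than in every mini GIST, as were CD34 (-4.48), a surface glycoprotein used as a GIST marker, PODN (-4.26), a small leucine-rich proteoglycan, and COL8A1 (-3.78), a collagen chain. The others of the 10 lowest were BARX1 (-5.69), a homeobox gene of stomach mesenchyme, GREM1 (-4.57), an antagonist of bone morphogenetic proteins, LEFTY2 (-4.17), of the TGF-beta family, and PI16 (-3.98). Each was lower in 6 of 7 overt GIST than in every mini GIST. BARX1 ranged from 0 to 1472 RPM among overt GIST and from 1368 to 3517 RPM among mini GIST (adjusted p = 0.0398).

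The genes with the highest fold changes in overt GIST included the homeobox genes NKX3-2, HOXC9 and HOXD9. NKX3-2, a homeobox gene of gut and axial mesenchyme, averaged 420 ± 225 RPM in overt and 53.0 ± 76.2 RPM in mini GIST (3.65 ± 0.56, limma adjusted p = 0.00305). It exceeded every mini GIST in 6 of 7 overt GIST. HOXC9 (2.84 ± 0.56, adjusted p = 0.0126) and HOXD9 (2.66 ± 0.55, adjusted p = 0.015), homeobox genes that pattern the posterior body axis, exceeded every mini GIST in 7 and in 6 of 7 overt GIST. HOXC9 averaged 26.3 ± 20.2 RPM in overt and 1.78 ± 0.97 RPM in mini GIST. AMH, the anti-Müllerian hormone (2.59), was above every mini GIST in 7 of 7 overt GIST. SLC4A1, the band 3 anion exchanger of red blood cells, averaged 1289 ± 916 against 117 ± 110 RPM (3.44 ± 0.73, adjusted p = 0.0169). The haemoglobin gene HBB averaged 20.7 ± 14.2 against 39.4 ± 62.7 RPM (0.08 ± 0.73, adjusted p = 0.971). The others of the 10 highest were BASP1 (3.09), NT5DC2 (2.81), PAQR8 (2.61), a membrane progestin receptor, VAPA (2.60), a membrane protein of the endoplasmic reticulum, and PLEKHG4B (2.56). SLC4A1, PAQR8 and VAPA were each lowest among overt GIST in tumour 6 (88.7, 69.3 and 17.0 RPM). Among mini GIST each was highest in tumours 1 and 2. They may therefore not be separate differences, and the cause was not tested.

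Across all tested genes, 455 differed between the groups (limma with Benjamini-Hochberg adjustment over 12749 genes), 86 higher and 369 lower in overt GIST, and 419 of these differed by at least 1 on the log2 scale (83 higher, 336 lower). All 7 overt GIST lay above all 6 mini GIST for 54 genes and below them for 200, together 1.99% of genes where chance gives 0.12%. The share of calls that were higher in overt GIST, 18.9%, depended on the scaling and on single tumours. It was 34.2% without overt GIST 6 (191 higher, 367 lower) and 56.2% without overt GIST 6 and 7 together (523 and 408), which was added after the data were seen. It was 30.3% with TMM factors (149 higher, 343 lower), 31.2% with median-of-ratios factors (158 and 349) and 38.2% after quantile normalization (260 and 421). It was 46.8% with edgeR on the recovered reads (225 and 256) and 53.5% with DESeq2 (731 and 635). With the mean of smooth muscle genes in each tumour as a covariate, limma called 0 genes (868 at an unadjusted p under 0.05), and an exact rank-sum test also called 0 (2004 unadjusted). With edgeR, calls were lost for DPT (adjusted p = 0.0791), BARX1 (0.221), CD34 (0.0722), COL8A1 (0.114), PI16 (0.069) and BASP1 (0.0501). The BARX1 call was lost with DESeq2 as well (0.189). On the recovered reads the fold change was -4.43 with both tools for DPT, and -2.60 with edgeR and -2.62 with DESeq2 for BARX1. The number of genes called moved by over 1.5 times on leaving out overt GIST 1 (724), overt GIST 4 (279) or mini GIST 1 (295), 2 (235), 3 (288), 4 (253) or 5 (179). Among the genes named above, calls were lost on leaving out single libraries for BARX1 (9 of the 13 libraries, adjusted p up to 0.0874 without mini GIST 5) and NT5DC2 (11 libraries, up to 0.0864 without mini GIST 2). Leaving out mini GIST 5 also ended those of VAPA (0.0825), PLEKHG4B (0.0865), COL8A1 (0.0791), PI16 (0.0695), PAQR8 (0.0647), BASP1 (0.0584), AMH (0.0519) and SLC4A1 (0.0507). Other libraries did so too for VAPA and PLEKHG4B (7 in all each), COL8A1 (6), PI16 (5) and PAQR8 (5).

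**Figure D2:**
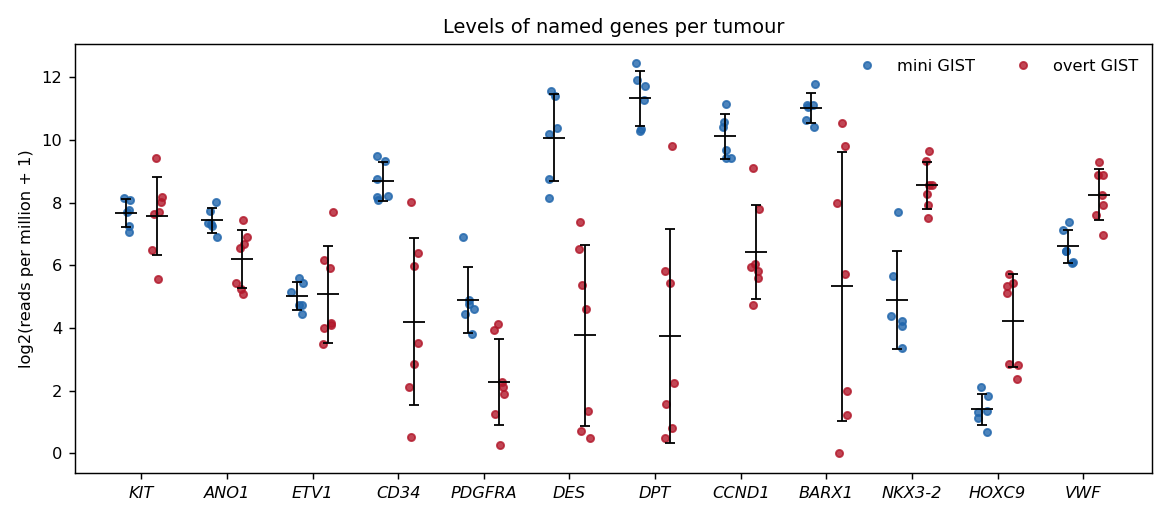
Expression per tumour of 12 named genes as log2(RPM + 1) (vertical axis) in mini GIST (blue, n = 6) and overt GIST (red, n = 7). Points are tumours and bars the mean ± SD on that scale. KIT levels overlap, while DES, DPT, CD34 and CCND1 are lower in all 7 overt GIST than in every mini GIST and HOXC9 is higher.

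KIT, the receptor tyrosine kinase that defines most GIST, did not differ detectably. It averaged 254 ± 210 RPM in overt and 210.0 ± 60.7 RPM in mini GIST (log2 fold change -0.09, 95% interval -1.08 to 0.89, limma adjusted p = 0.938). ETV1, the transcription factor of the interstitial cell lineage (0.06, -1.14 to 1.26, adjusted p = 0.973), and PRKCQ, protein kinase C theta (0.32, -0.57 to 1.21, adjusted p = 0.727), were not past the threshold either. ANO1, the calcium-activated chloride channel stained as DOG1, averaged 85.6 ± 51.6 against 177.1 ± 49.4 RPM and missed the threshold (-1.24 ± 0.37, adjusted p = 0.0766; 0.0217 without overt GIST 1). Of the 18 measured genes of the GIST and interstitial cell of Cajal lineage list, 4 fell and 14 did not pass the test (7 lower adjusted over the list alone). They were BARX1, CD34, PLAT, encoding tissue plasminogen activator (-3.47 ± 0.61, adjusted p = 0.00713), and PDGFRA, the receptor mutated in place of KIT in some GIST (-2.63 ± 0.60, adjusted p = 0.0241). The PDGFRA call was lost without mini GIST 4 (0.0549) and with edgeR (0.0625). The list was called lower by camera with a preset correlation (adjusted p = 0.0247; 0.12 without overt GIST 5 and 0.444 with the smooth muscle mean as a covariate) but its median was -0.15, and adjusted p = 0.598 with an estimated correlation. Of the 16 genes of the KIT-MAPK pathway output list only CCND1 passed limma's test, and 2 were lower adjusted over the list alone. EdgeR called 2 of the 16 and DESeq2 4. ETV5 missed limma's threshold (-1.20 ± 0.34, adjusted p = 0.0579) but passed with edgeR (0.0353) and DESeq2 (0.00284). The KIT-MAPK list was not called (camera adjusted p = 0.106), although it passed without overt GIST 3 (0.0315) or mini GIST 3 (0.0224).

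Smooth muscle genes were lower in overt GIST as a group. Of 19 measured members 8 fell and 11 did not pass (16 lower adjusted over the list alone), with a median log2 fold change of -1.88. Besides DES they included MYLK, myosin light chain kinase (-2.87 ± 0.57, limma adjusted p = 0.0126), PGM5, a phosphoglucomutase relative found at muscle adhesions (-2.95 ± 0.64, adjusted p = 0.0195), and CNN1, calponin (-3.55 ± 0.85, adjusted p = 0.0283). The PGM5 call was lost without mini GIST 5 (0.057) and with edgeR (0.0734), as was that of CNN1 with edgeR (0.0872). ACTA2, smooth muscle actin, stood at 29.9 ± 19.4 RPM in overt and 35.4 ± 31.5 RPM in mini GIST (0.02 ± 0.52, adjusted p = 0.99). The mean of the list per tumour was 5.16 ± 0.81 in overt and 7.16 ± 0.69 in mini GIST on the log2 scale (exact permutation p = 0.00175, adjusted over 25 lists 0.034). Camera called the list with a preset correlation (adjusted p = 7.83e-11), with adjusted p = 0.298 with an estimated correlation.

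Markers of other cell types moved in both directions. Of 13 Schwann cell and enteric glia genes with deposited values, 6 passed the filter on low values. These 6 averaged 2.66 ± 0.36 in overt and 3.57 ± 0.82 in mini GIST (exact permutation p = 0.00408, adjusted 0.034). The 1 member that fell was S100B (-2.82 ± 0.57, limma adjusted p = 0.0135; 0.0607 with edgeR). Camera did not call the list (adjusted p = 0.0643), although it passed without overt GIST 4 (0.0198) or 7 (0.0427) or mini GIST 1 (0.0272), 2 (0.0381) or 3 (0.0217). The endothelial list was higher in overt GIST, with a mean of 4.87 ± 0.44 against 3.99 ± 0.23 (exact permutation p = 0.00291, adjusted 0.034). Of its 15 genes 2 rose (4 adjusted over the list alone). VWF, von Willebrand factor (1.66 ± 0.36, limma adjusted p = 0.0188), and EMCN, the endothelial sialomucin endomucin (2.11 ± 0.48, adjusted p = 0.0241), were each above every mini GIST in 6 of 7 overt GIST. The VWF call was lost without mini GIST 5 (0.0563), and the EMCN call without overt GIST 4 (0.0506) or mini GIST 1 (0.0525), 2 (0.0567), 3 (0.0515) or 5 (0.0637). Camera called the endothelial list with a preset correlation (adjusted p = 0.000206), and adjusted p = 0.332 with an estimated correlation. These 3 lists were the ones past the exact test of means per tumour. On leaving out overt GIST 1, 5, 6 or 7 or mini GIST 2, 4, 5 or 6 no list stayed past the adjusted threshold (0 of 25, exact permutation). The unadjusted exact p stayed at or below 0.00433 for smooth muscle, 0.00758 for endothelial genes and 0.0152 for Schwann cell and enteric glia genes.

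Of the 12 antigen presentation genes 1 fell, CD74, the class II invariant chain (-1.95 ± 0.43, limma adjusted p = 0.0201; 0.0565 without mini GIST 5), and 3 were lower adjusted over the list alone. None of the 19 interferon response genes passed with limma (5 at an unadjusted p under 0.05), edgeR or DESeq2. Of these MX1 (-1.22 ± 0.44, adjusted p = 0.133, and 0.031 without overt GIST 2) and IFI27 (-1.40 ± 0.56, adjusted p = 0.17) had the smallest unadjusted p. Camera with a preset correlation called both lists lower (adjusted p = 0.00356 each), with adjusted p = 0.598 with an estimated correlation for antigen presentation and 0.633 for interferon response. The interferon call was also lost without overt GIST 6 and 7 together (0.0573). Leukocyte lists were not called: T and NK cell (camera adjusted p = 0.578), B and plasma cell (0.733), macrophage (0.56) and neutrophil (0.91). The B and plasma cell list had a median of 0.36 but a mean of -0.19 and a downward test, and its 1 member that fell was DERL3, of the endoplasmic reticulum degradation pathway (-2.84 ± 0.62, limma adjusted p = 0.019, and 0.0657 with edgeR). The 23 fibroblast and extracellular matrix genes had a median of -0.55 and camera adjusted p = 0.0723, which passed without overt GIST 1 (0.0428), 2 (0.018), 4 (0.0431) or 7 (0.0291) or mini GIST 2 (0.0381) or 3 (0.0224). Their 1 member that fell was ELN, elastin (-3.67 ± 0.72, limma adjusted p = 0.0123, and 0.0651 with edgeR). The gastric and intestinal epithelium (camera adjusted p = 0.256), enteric neuron (0.263) and adipocyte (0.56) lists were not called. Only 6 of 26, 6 of 18 and 5 of 10 of their members with deposited values passed the filter on low values. Fewer than 5 members were measured for the mast cell (2), red blood cell (4) and mitochondrially encoded (0) lists, which were not tested.

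Proliferation genes were spread widely among overt GIST. The filter on low values kept 26 of the 43 members with deposited values. None of the 26 passed limma's test (3 at an unadjusted p under 0.05, 0 called by edgeR, 6 by DESeq2). Camera with a preset correlation called the list higher (median 0.63, adjusted p = 0.000534), with adjusted p = 0.598 with an estimated correlation and 0.659 with the smooth muscle mean as a covariate. The means per tumour were 3.35 ± 0.80 in overt and 2.74 ± 0.34 in mini GIST (exact permutation p = 0.114). MKI67, the Ki-67 antigen, ranged from 1.51 to 32.1 RPM in overt and from 4.10 to 7.44 RPM in mini GIST (0.52 ± 0.54, adjusted p = 0.644). TOP2A, topoisomerase II alpha, averaged 6.84 ± 5.99 against 1.12 ± 0.98 RPM and missed limma's threshold (1.53 ± 0.54, adjusted p = 0.126; 0.0479 without overt GIST 6), though it passed with DESeq2 on the recovered reads (adjusted p = 0.00863). The 17 GIST progression tumour suppressors were not called as a list (camera adjusted p = 0.56). Of these NF2, encoding merlin, fell (-1.56 ± 0.37, limma adjusted p = 0.0288) and was lower in all 7 overt GIST than in every mini GIST. The NF2 call was lost on leaving out 6 of the 13 libraries (up to 0.0763, without mini GIST 5). CDKN2A, encoding p16 (-0.35, 95% interval -2.05 to 1.35), and DMD, encoding dystrophin (-0.18, -0.92 to 0.56), did not differ detectably (adjusted p = 0.852 and 0.821).

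Of the metabolic and stress lists, camera with a preset correlation called nuclear-encoded oxidative phosphorylation higher (median 0.35, adjusted p = 0.00206, and adjusted p = 0.598 with an estimated correlation). It called immediate early response lower (median -0.62, adjusted p = 0.0247, and adjusted p = 0.691 with an estimated correlation). None of their 49 and 18 members passed limma's test. At an unadjusted p under 0.05, 7 and 6 passed, edgeR called 0 in each list, and DESeq2 called 2 and 3. The immediate early call was lost without overt GIST 3 (0.0794), 5 (0.119) or 7 (0.0725) or mini GIST 5 (0.0766) or 6 (0.208), without overt GIST 6 and 7 together (0.178), with a filter at 5 RPM (0.0518) and with array weights (0.22), and the median turned to 0.64 with the smooth muscle mean as a covariate. Glycolysis (0.56), hypoxia response (0.91), heat shock response (0.32), IGF and RTK signalling (0.276) and hedgehog and WNT pathway (0.287) lists were not called by camera. The cytosolic ribosomal protein list was not called either (0.167) but passed without overt GIST 1 (0.000148) or 3 (0.00776) or mini GIST 5 (0.0466). Of the hypoxia list NDRG1 fell (-1.47 ± 0.32, limma adjusted p = 0.0201), a call lost without mini GIST 2 (0.054) or 5 (0.0584). CA12, a carbonic anhydrase of the same list, stood at 20.2 ± 15.5 RPM in overt and 2.56 ± 1.32 RPM in mini GIST and missed limma's threshold (2.13 ± 0.57, adjusted p = 0.0506). CA12 passed with edgeR (0.0163) and DESeq2 (1.07e-05) and without overt GIST 6 (0.00659) or 7 (0.0421). Adjusted over the list alone, 1 hypoxia gene was higher and 1 lower. Of the heat shock and IGF lists the members that fell were CRYAB, the small heat shock protein alpha-B crystallin (-2.78 ± 0.57, adjusted p = 0.0142), and IGFBP5, an insulin-like growth factor binding protein (-2.57 ± 0.44, adjusted p = 0.00601). IGFBP5 was lower in all 7 overt GIST than in every mini GIST.

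**Figure D3:**
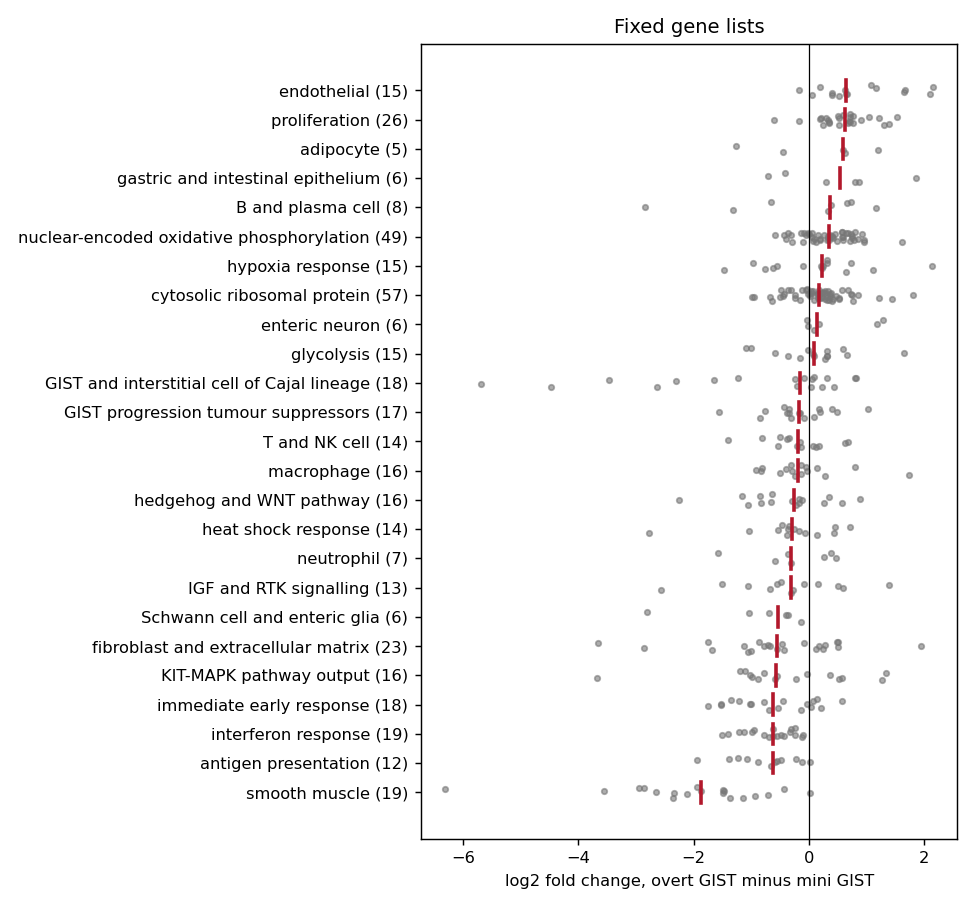
Log2 fold change, overt minus mini GIST (horizontal axis), of each tested member (grey points) of the 25 lists, with the number of members in brackets and the median as a red line. The smooth muscle list has the lowest median, -1.88, and the endothelial list the highest, 0.65.

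Genes were also grouped by chromosome, since losses of 1p, 14, 15 and 22 recur in GIST. Camera with a preset correlation called 4 of 24 sets: genes on chromosome 22 (median log2 fold change -0.36, adjusted p = 2.31e-05), 1p (-0.27, 2.58e-05) and 15 (-0.26, 0.00449) were lower and those on chromosome 8 higher (0.23, 0.00449). No set was called with an estimated correlation (adjusted p = 0.989 for each). On 1p, 47 of 687 tested genes fell and 0 rose by limma, and 69.9% had a negative fold change, against 49.2% of all tested genes. On chromosome 22, 22 of 341 fell and 1 rose, and 70.4% were negative. On chromosome 15, 22 of 368 fell and 0 rose. On chromosome 8, 4 of 406 rose and 9 fell, and 30.5% were negative. Of all 12749 tested genes 86 rose and 369 fell, so more falling than rising calls on chromosome 8 do not run against its set. Chromosome 14 (-0.04, adjusted p = 0.799), chromosome 13 (-0.17, 0.127) and 9p (-0.08, 0.851) were not called. An exact permutation test of the mean per tumour relative to all tested genes, added after the data were seen, called none (0 of 24). By it, 1p stood at -0.19 ± 0.19 in overt and 0.09 ± 0.02 in mini GIST (exact p = 0.00641, adjusted 0.0769) and chromosome 8 at -0.13 ± 0.21 and -0.37 ± 0.08 (exact p = 0.0035, adjusted 0.0769). Chromosome 22 stood at 0.50 ± 0.28 and 0.79 ± 0.11 (exact p = 0.0466, adjusted 0.224). The chromosome 8 call was lost without overt GIST 3 (median 0.08, camera adjusted p = 0.0661) and with the smooth muscle mean as a covariate (median 0.13, adjusted p = 0.16). The chromosome 15 call was lost without overt GIST 6 and 7 together (median -0.03, adjusted p = 0.126). Without these 2 tumours the 1p median also shrank to -0.09 (adjusted p = 0.00323) and that of chromosome 8 grew to 0.46 (0.00242), while chromosome 22 stood at -0.32 (1.04e-06). Chromosome 13 passed without overt GIST 2 (0.046) or 4 (0.0232) or mini GIST 5 (0.0339). Chromosomes are those of the GRCh38.p14 gene table, used for grouping only. Its gene starts told apart the arms of chromosomes 1 and 9, at approximate centromere positions.

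**Figure D4:**
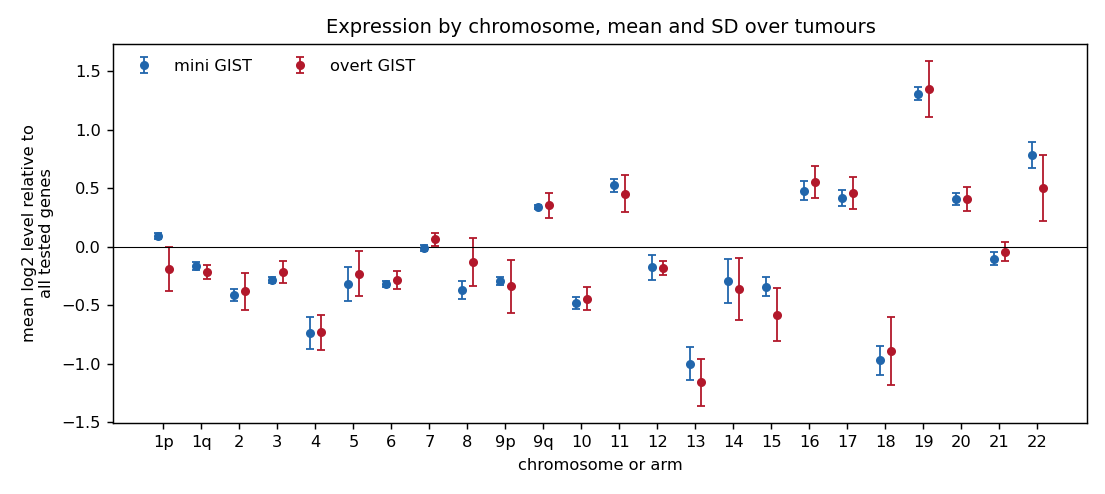
Mean log2(RPM + 1) of the tested genes of each chromosome or arm (horizontal axis), minus the mean of all tested genes of the same tumour (vertical axis), as the mean ± SD over 6 mini GIST (blue) and 7 overt GIST (red). For 1p the mean is -0.19 in overt and 0.09 in mini GIST.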

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

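The tests of the desmin ratio, of the other smooth muscle genes and of BARX1 against HOXC genes, and the thinning to equal depth, were chosen only after the results were seen. Of 110 groups of values checked, 8 held a tumour far from the rest of its group, and chance alone gives about 1 in 20. On the log2(RPM + 1) scale, overt GIST 1 was highest for GREM1 (4.541, the others at most 0.9105) and PI16 (4.91, at most 1.174). Overt GIST 6 was lowest for PAQR8 (6.135, the others at least 8.661) and for the Schwann cell and enteric glia mean (1.921, at least 2.612), and overt GIST 5 was highest for the glycolysis mean (8.42, at most 7.315). Mini GIST 4 was highest for BASP1 (5.741, at most 2.706) and PDGFRA (6.909, at most 4.897), and mini GIST 3 for the interferon response mean (4.946, at most 4.406).

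Desmin and most smooth muscle genes were lower in overt GIST, and smooth muscle cells inside the small mini GIST cores are a candidate explanation. The median of the 18 measured smooth muscle genes other than DES was -1.69, and 17 of them were lower by more than their standard error, with ACTA2 the exception. The log2 ratio of DES to MYH11, with 1 RPM added to each, was 3.86 ± 0.87 in mini and -0.08 ± 1.21 in overt GIST. The difference was -3.95 (exact permutation p = 0.00058, the smallest possible). In overt GIST 3, 5 and 7, DES stood at 0.394, 0.627 and 1.53 RPM, so the added 1 RPM weighs on their values. Muscle cells as the only source of both genes would keep the ratio only if they were of the same kind in both groups. MYH11 in overt GIST stood at 26.1% of its mini GIST mean, so MYH11 made by the tumour cells may set part of that ratio. Admixture and a muscle programme of the mini GIST cells themselves cannot be told apart, because the cell content of the cores is not known and the source of the tissue is confounded with the group.

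BARX1 was lower and HOXC9 higher in overt GIST, and a mixture of tumours from different positions along the gut within the overt group is a candidate explanation, since BARX1 marks the stomach and posterior HOX genes the distal axis. Among the 7 overt GIST, BARX1 and the mean of HOXC9, HOXC10 and HOXC11 ran in opposite directions (Spearman rho = -0.786, exact permutation p = 0.048; Pearson r = -0.907, exact permutation p = 0.012; r = -0.855 without the 2 tumours farthest from the median). These 3 genes were picked after their values were seen and HOXC10 was below the filter on low values, but over all 6 tested HOXC genes rho was -0.964 (exact permutation p = 0.0028, adjusted over 3 relations 0.0083; Pearson r = -0.977, p = 0.00099) and over HOXC9 and HOXC11 alone -0.786 (exact permutation p = 0.048, adjusted 0.048). That relation goes with the explanation, but HOXD9 was not part of it. BARX1 was highest among overt GIST in tumours 1 and 5 (1472 and 898 RPM). There HOXC9 stood at 6.296 and 4.179 RPM, above the mini GIST maximum of 3.299 RPM. HOXD9 stood at 15.01 and 34.69 RPM, above the mini GIST maximum of 8.691 RPM. A mixture of positions alone does not account for these values if such tumours match mini GIST in position. The tumour sites are not used here, and a difference between overt and mini GIST as such stays open. With the smooth muscle mean as a covariate, BARX1 went from -5.69 ± 1.46 (limma adjusted p = 0.0398) to -5.61 ± 2.60 (adjusted p = 0.72), so the call ended through the wider error and muscle content cannot be told apart from the group for this gene.

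The spread among overt GIST exceeded that among mini GIST by 0.0829 in mean distance. Unequal depth was argued against: with all libraries thinned to the shallowest, the difference was 0.0784 (exact permutation p = 0.00058). A single aberrant overt library was argued against as well, since leaving out each library in turn left at least 0.0788 (exact permutation p = 0.00216 there). Tumour stage, site and differences in how clinic and autopsy tissue was handled stay open and were not tested.

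Chance can be excluded for the number of genes: the real grouping gave 455 and was the 1 of 100 splits that reached it, the highest other split giving 1. It cannot be excluded for the number of lists called by camera with a preset correlation (8; 42 of 100 splits gave as many, the highest other 12) or of chromosome sets (4; 57 of 100, the highest other 10).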

How the results depend on the processing

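Thinning, leaving out overt GIST 6 and 7 together and the exact test of chromosome means were alternatives chosen only after the results were seen. Of 455 genes (86 higher, 369 lower; 419 by at least 1 on the log2 scale), array weights gave 856 (257, 599; 741), DESeq2 1366 (731, 635; 1217; 511 without an adjusted p) and the removal of overt GIST 6 and 7 gave 931 (523 higher, 408 lower; 855). The smooth muscle covariate gave 0 in every count (868 at an unadjusted p under 0.05 with limma) and so did the exact rank-sum test (2004 unadjusted), against 2543 unadjusted with limma, 481 calls with edgeR and 1366 with DESeq2. Neither 0 shows that genes do not differ. The covariate itself differed between the groups, and even fully separated genes fell short with the rank-sum test. Genes higher numbered 55 with no filter, 149 with TMM, 260 with quantile, 158 with median-of-ratios scaling, 136 with genes detected as covariate and 225 with edgeR. Of the 455, 305 were also called by edgeR and 417 by DESeq2. The median over all genes shifted to 0.114 with edgeR, 0.108 with DESeq2 and 0.148 without overt GIST 6 and 7, from 0.009. Leaving out single libraries gave 179 (without mini GIST 5) to 724 genes (without overt GIST 1), 26 (mini GIST 5) to 191 higher (overt GIST 6), 153 to 549 lower, and 177 to 633 by at least 1 on the log2 scale; between these, counts were 279 without overt GIST 4 and 295, 235, 288 and 253 without mini GIST 1 to 4. With thinning, 359 genes were called, 339 of them among the 455. An estimated correlation left 0 lists and 0 chromosome sets, and the exact test per tumour left 0 chromosome sets. Leaving out single libraries gave 0 to 3 lists past the exact test of means, 6 to 11 lists by camera and 3 to 5 chromosome sets. The smooth muscle covariate reversed the medians of the fibroblast and extracellular matrix (0.532) and immediate early (0.637) lists. The smooth muscle list itself went to 0.278, which says nothing of its stability because the covariate is made of its own members. Across the alternatives run on the 99 named genes, 2468 values stayed on their side of the threshold (2438 with the same sign, 30 with the sign turned), 176 lost the call and 104 gained it. For single lists and chromosome sets 1205 stayed (1102 with the same sign, 103 turned), 27 lost the call and 29 gained it. Each turned value counted here was not called in either setting. The separation and spread of the groups kept their direction and stayed past the threshold in all alternatives run. Except where the construction shows it (fewer samples, a wider error with the covariate), the cause was not tested. No paired analysis was possible because replicate numbers only follow accession order. Depth limits low genes: 3 reads in the shallowest library stand at 1.45 RPM.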

Other observations

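The gene groups here were chosen after the data were seen. Genes of elastic fibres were lower in overt GIST: of 20 measured members 6 fell and 0 rose by limma, with a median log2 fold change of -1.06. Besides ELN they were LTBP1 (-2.78 ± 0.51, SE, adjusted p = 0.00837), LTBP2 (-2.30) and LTBP3 (-1.43), latent TGF-beta binding proteins of the matrix, LOXL1 (-2.73), which cross-links elastin, and EMILIN3 (-3.04). With edgeR on the recovered reads the calls of ELN (adjusted p = 0.0651), LTBP3 (0.0721), LOXL1 (0.0597) and EMILIN3 (0.13) were lost, and that of EMILIN3 with DESeq2 as well (0.123). LTBP1 was lower in all 7 overt GIST than in every mini GIST, whereas FBN1, encoding fibrillin, stood at 172.7 ± 80.5 RPM in overt and 146.0 ± 64.7 RPM in mini GIST (0.18 ± 0.39, adjusted p = 0.845). Camera called the set lower with a preset correlation (adjusted p = 4.45e-06) and with adjusted p = 0.0103 with an estimated correlation, and the mean per tumour differed by -1.27 (exact permutation p = 0.00117, adjusted over 2 sets 0.00233). The smooth muscle mean fell by 2.00 in the same comparison. Of 20 complement genes 4 fell and 0 rose: SERPING1, the C1 inhibitor (-2.82 ± 0.44, limma adjusted p = 0.00315), C1R (-1.55), C2 (-2.69) and C5AR1 (-1.53). The C1R call was lost with edgeR (0.13) and DESeq2 (0.0854). The C1q chains of macrophages did not pass (C1QA 0.28 ± 0.50, adjusted p = 0.805). The complement set had camera adjusted p = 0.0119, adjusted p = 0.11 with an estimated correlation, and a difference of -0.59 per tumour (exact permutation p = 0.00583, adjusted 0.00583). Because genes of both sets had been seen among the calls before the sets were drawn up, these p-values are not independent evidence. Both medians stayed below 0 under TMM, quantile and median-of-ratios scaling and with edgeR and DESeq2, from -1.07 to -0.98 for elastic fibres and from -0.25 to -0.14 for complement.

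Few HOX genes passed singly. The 8 HOXB genes that passed the filter had a median of -1.36. HOXB4 (-1.51 ± 0.40, limma adjusted p = 0.0444, and 0.0772 with edgeR) was the 1 that fell, and HOXB13 (0.58 ± 0.91) ran the other way. The 6 HOXC genes that passed the filter had a median of 1.03, with HOXC9 the 1 that rose. Camera with a preset correlation gave adjusted p = 0.00344 and 0.00783, and adjusted p = 0.187 for each with an estimated correlation. Under the same alternatives the HOXB median lay between -1.39 and -0.49 and the HOXC median between 1.06 and 2.37. HOXC11 ranged from 0.376 to 280 RPM among overt GIST but from 0.193 to 0.882 RPM among mini GIST, and its mean difference missed the threshold (2.80 ± 1.06, limma adjusted p = 0.15). HOXB7 ranged from 2.42 to 225 RPM in overt and from 59.2 to 147 RPM in mini GIST.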
